A study of Mus musculus with 16 samples.

How the data were processed

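The material was H3K27ac ChIP-seq and DNase-seq of CD4 T cells from mice with floxed Bcl11b and a tamoxifen-inducible Cre, grown under Th2 conditions with 4-OHT (KO) or without it (WT). ChIP used a commercial histone kit and antibody, and DNase-seq followed a protocol developed for small cell numbers, per the labels' protocols. The labels call the isolated cells naive and also give a sort on high CD44, a marker of activated cells, and this was left as stated. Groups were taken from the labels, with 2 replicates of each assay, stage and genotype. No sample that kept the gene was treated with 4-OHT, so genotype and exposure to 4-OHT cannot be separated. The labels do not say that replicates came from separate cultures or animals, so p-values can measure no more than the spread between these samples, which may be technical.

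Reads were processed with CASAVA 2.18, Bowtie2 and SICER 1.1 on the build mm9, per the submitters' processing notes. SICER joins enriched 200-bp windows across gaps into islands, which suits broad marks. The deposited lists give each island's chromosome, start, end and a score, which is the authors' own value from the caller. The score was used only to rank or filter islands within a list. The lists were called for each library on its own, and no control library, duplicate rate or read number is given in the sources used here. Without counts the depth is unknown, and an absent island shows only that a list does not hold it. The gene table at hand was of another build, coordinates were not converted, and regions are therefore named by position. Bcl11b and other genes were not analysed here by coordinate, and the deleted part of Bcl11b was not checked.

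The main tests were set before the data were examined, and so were the groups, the naming rule and most other settings. With no mm9 annotation the planned fallback was used, a fit on 10-kb bins in place of gene loci. The kb of each bin covered by islands were taken as log2(kb + 0.5), for bins covered in at least 2 of the 8 libraries of an assay. Libraries were centred on the median of bins covered in all 8. All 4 groups of an assay were fitted with limma 3.58.1 (lmFit, eBayes with a trend), with contrasts for KO against WT at each stage, their average, their difference and late against early WT. Bins with a Benjamini-Hochberg adjusted p under 0.05 were called, and called bins are those said to rise or fall. Where both lists of a group held no island in a bin, the spread of that group was set by the floor and the centring alone. The same holds where both lists filled the 10 kb of a bin, which can rise no further. The p-value then rested mainly on the other groups and on the spread that eBayes shares across bins. Log2 changes are on the log2(kb + 0.5) scale, and for bins listed at 0 in a group the kb of both groups are given and no fold. The closing section gives log2 values of such bins for interactions and changes of sign, and these depend on the pseudocount.

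Regions were made by merging islands of the 4 libraries of a stage that overlapped or touched. A region counted as found in KO alone if both KO and neither WT library had an island in it, and likewise for WT. Totals per library were compared with exact two-sided permutation tests. Named regions were the 5 with the highest mean score percentile, and named bins the 8 with the largest rise and fall among those called (10 for time). For brevity the text gives the first 3 of these bins per direction at each stage at most, and the first 2 for time and for the average of H3K27ac, a reduction made after the data were seen. The early KO change and the change with time share the early WT libraries. Their covariance was set beside that of simulated unchanged groups with a shared control, over 20 seeded draws. All simulated groups, the control included, were normal noise with the spread of each bin over all groups, without floor or cap. If early WT libraries vary more than that, this baseline is too low.

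Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3. The bin fit was tested on simulated data. With 200 of 39126 H3K27ac bins changed by a log2 of 2 in early KO, 57.5% were called, with 9 unchanged bins, and 0 were called at a log2 of 1. In DNase (37586 bins) 0 of 200 were called at either size. The changed bins were chosen for middle coverage, with normal noise around the mean of all libraries. Changes of these sizes in bins of that kind were thus mostly out of reach of the DNase fit. Most bins called in the data had no island in the lower group, and these rates do not describe them.

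The alternatives were no centring, quantile normalization, equal list lengths, the upper 50% of each list by score, a pseudocount of 2 kb, no filter on bins, a replicate block, at least 50% of a region covered, islands within 1 kb merged, and each library left out in turn. Bins of 50 kb and centring on the mean were added after the data were seen. Gene lists and 50-kb flanks around genes, planned for an annotated build, were not run.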

Results

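CD4 T cells of C57BL/6 mice that carried floxed Bcl11b alleles and a Cre recombinase switched on by 4-hydroxytamoxifen (4-OHT) were driven towards the T helper 2 (Th2) fate in culture. Bcl11b is a zinc finger transcription factor of the T lineage. The title of the series pairs it with GATA3, the regulator that defines Th2 cells, and asks how it bears on the Th1 and Th2 programmes. Early cells had 4 days of Th2 culture, with 4-OHT (knockout, KO) or without it (wild type, WT). Late cells had 4 days of Th2 culture, 1 day of rest in medium with IL-2 and 4 more days of Th2 culture, and 4-OHT was given only in the second culture. Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured by ChIP-seq, and open chromatin by DNase-seq. Each assay had 8 libraries in 4 groups, 2 per group, so 16 libraries in all. Each library came as a list of enriched islands on the mouse build mm9, without read counts, so the sequencing depth behind each list is unknown.

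H3K27ac islands covered a similar length in both genotypes, whereas the DNase lists of late KO cells were short. The 8 H3K27ac lists held 26548 to 32112 islands and covered 100.9 to 111.7 Mb. Covered length averaged 106.4 ± 4.6 Mb in KO and 103.8 ± 2.4 Mb in WT (SD, n = 4 per genotype, exact two-sided permutation p = 0.3429). DNase islands covered 56.6 ± 14.5 Mb in early WT, 40.3 ± 12.7 Mb in early KO, 48.6 ± 5.4 Mb in late WT and 26.0 ± 0.2 Mb in late KO cells (SD, n = 2 per group). Over both stages DNase islands covered 33.2 ± 11.0 Mb in KO and 52.6 ± 10.1 Mb in WT (SD, n = 4 per genotype, exact two-sided permutation p = 0.0857, where 0.0286 is the smallest p that 4 against 4 allows). That difference did not pass the test. Within a stage 2 libraries against 2 are too few for an exact permutation test to pass, and no other test was run on these totals.

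**Figure D1:**
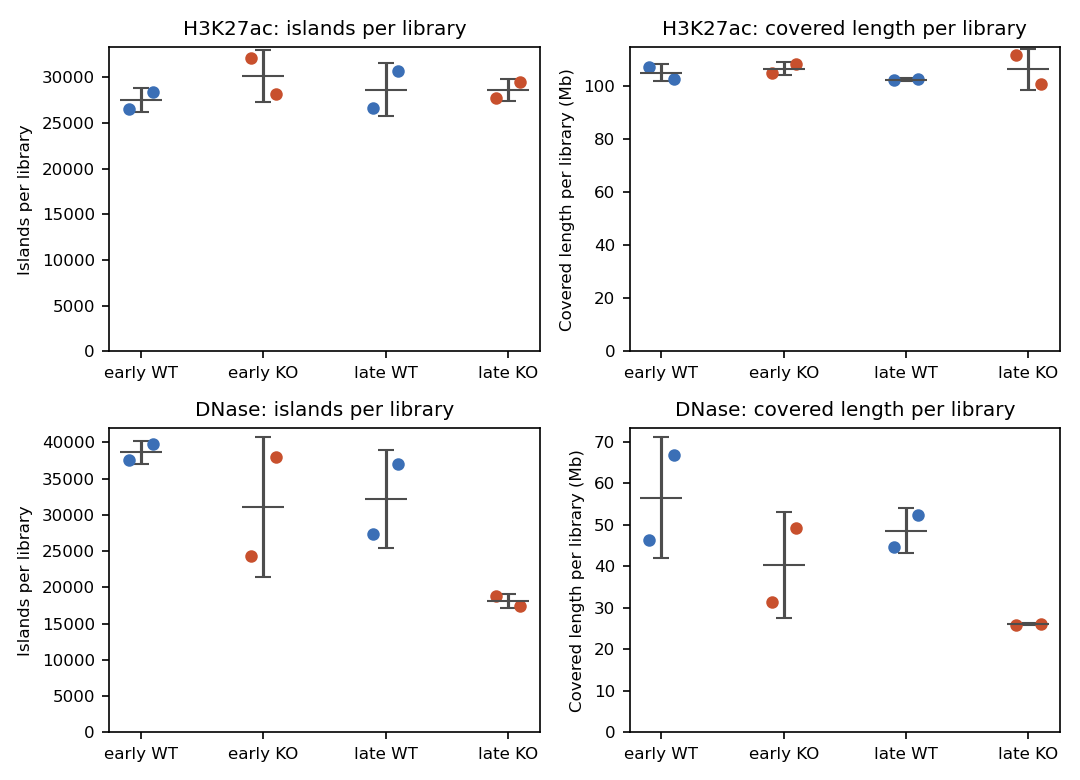
Islands per library (left) and the length they cover in Mb (right) for H3K27ac (top) and DNase (bottom); points are libraries, lines and bars the mean and SD of each group (n = 2). The late KO DNase libraries lie lowest, at 25.9 and 26.2 Mb.

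The first comparison asked what deletion during the first 4 days of Th2 culture did to H3K27ac. The acetylated regions of early KO and early WT cells differed more than replicates did, and more regions gained the mark than lost it. Of the 200-bp windows covered in either of 2 libraries, early KO and early WT libraries shared 62.5% on average (60.9% to 63.9%), against 76.1% between the early KO replicates and 70.3% between the early WT replicates. Of 33678 merged regions, 3515 were acetylated in both KO and neither WT library, 1413 in both WT and neither KO library, and 20950 (62.2%) in all 4. The other splits of the 4 libraries into pairs gave 31 to 313 regions. With lists cut to equal length, 2701 regions were found in KO alone and 1899 in WT alone. KO-only regions had a median width of 2200 bp, against 4000 bp for the regions in all 4 libraries. The KO-only region whose islands ranked highest lay on chromosome 13 at 113329001 to 113335400, at a mean percentile of 89.8 within the KO lists, where the median KO-only region stood at 20.8. A region on chromosome 19 at 25108201 to 25114200 came next, at percentile 82.9. Among WT-only regions the highest stood on chromosome 16 at 55504401 to 55508000 (percentile 60.4, set median 16.2), and the fifth on chromosome 10 at 128376601 to 128381800 (percentile 53.5).

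In 10-kb bins of the genome, 5711 of 39126 bins differed between early KO and early WT, 3588 higher and 2123 lower (limma, adjusted p under 0.05). Most of these bins held no island in the group with less coverage. Of the bins that rose, 2693 (75.1%) had no island in either WT library, and the mean coverage of the rising bins went from 0.58 to 2.81 kb. Of the bins that fell, 1193 (56.2%) had no island in either KO library, and the mean went from 3.9 to 1.15 kb. Bins covered in all 4 libraries changed by a median log2 of 0.88 where they rose (800 bins) and -0.90 where they fell (852 bins). The bin that rose most, on chromosome 4 at 107800001 to 107810000, was listed at 0 in both WT libraries and covered 8.3 ± 0.14 kb in KO (SD, n = 2, limma adjusted p = 0.000367). On chromosome 7 the bin at 148160001 to 148170000 was also listed at 0 in WT and covered 7.5 ± 0.99 kb in KO (SD, n = 2, limma adjusted p = 0.000343). A bin on chromosome 10 at 36940001 to 36950000 went from 0 to 7.9 ± 1.56 kb (SD, n = 2, limma adjusted p = 0.0222). The bins that fell most lay on chromosome 9 at 55960001 to 55970000 (9.7 ± 0.42 kb in WT, adjusted p = 0.0173), chromosome 1 at 93870001 to 93880000 (9.7 ± 0.42 kb, adjusted p = 0.0215) and chromosome 19 at 29200001 to 29210000 (9.3 ± 0.14 kb, adjusted p = 0.0227), each listed at 0 in both KO libraries (SD, n = 2, limma). The bins named on chromosomes 10, 1 and 19 lost the call without early WT replicate 1 or 2, early KO replicate 1 or 2, or late KO replicate 1 or 2, with adjusted p between 0.0618 and 0.112. The bin on chromosome 9 lost it without early WT replicate 1 or 2 or early KO replicate 1 or 2, with adjusted p between 0.069 and 0.0935. With the upper 50% of each list the bins on chromosomes 10 and 9 did not pass (adjusted p = 0.663 and 0.53), nor did the bin on chromosome 1 with quantile normalization (adjusted p = 0.0548).

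Neighbouring bins moved together over wide stretches in early KO cells, by a rule for runs that was set after the data were seen. On chromosome 4 the 80 kb from 119730001 to 119810000 held 7 bins that fell, and H3K27ac coverage there was 38.6 ± 5.7 kb in early WT and 2.2 ± 0.3 kb in early KO cells. Coverage of the 50 kb from 93850001 to 93900000 on chromosome 1 was 41.5 ± 6.6 kb in WT and 4.1 ± 0.7 kb in KO. The longest run that rose spanned 12760001 to 12820000 on chromosome 18, with 1.8 ± 0.0 kb in WT and 16.2 ± 1.1 kb in KO. On chromosome 9 the 50 kb from 114250001 to 114300000 held 4.7 ± 1.3 kb in WT and 19.1 ± 0.4 kb in KO (SD, n = 2 per group for each value). Runs of at least 3 called bins held 390 of the rising bins (10.9%, in 117 runs) and 197 of the falling bins (9.3%, in 59 runs). The count of regions found in KO alone was 6296 without early KO replicate 2, and that of regions found in WT alone was 2869 and 2385 without early WT replicates 1 and 2. The rising bins numbered 2384 without early KO replicate 1, and the falling bins 1041 and 1256 without early WT replicates 1 and 2. With only the upper 50% of each list by score, 2506 bins differed.

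**Figure D2:**
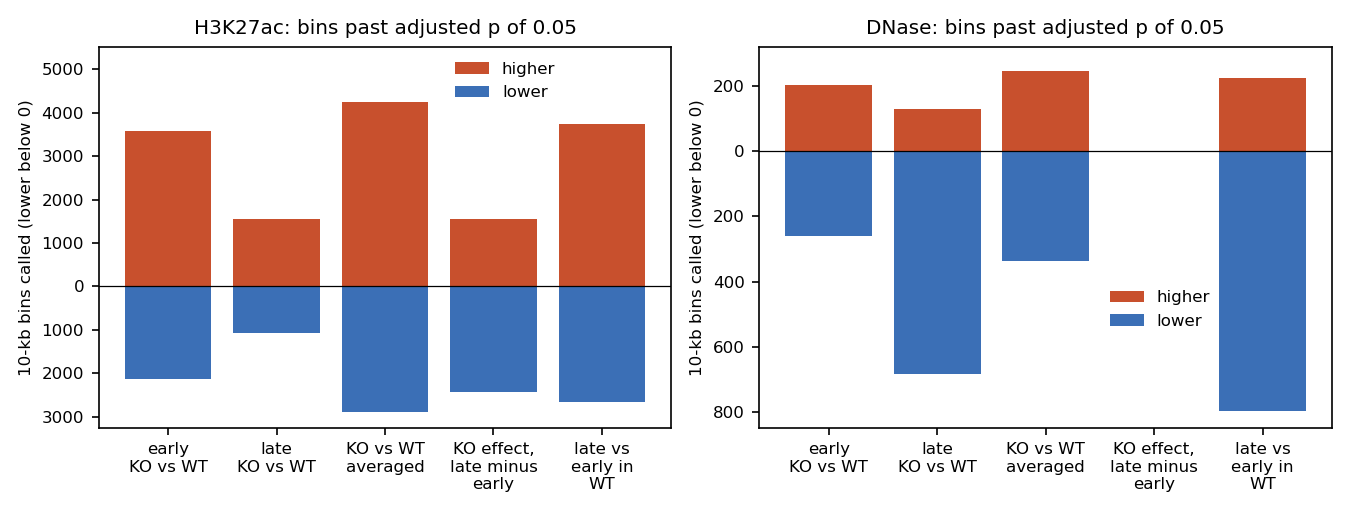
Number of 10-kb bins past an adjusted p of 0.05 in each comparison, for H3K27ac (left) and DNase (right); bars above 0 count bins that were higher and bars below 0 bins that were lower. The H3K27ac comparisons called from 2642 bins, for late KO against late WT, to 7130, for both stages averaged, and the DNase comparisons 0 to 1018.

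Deletion in cells that had already gone through a first Th2 culture was compared next. Late KO and late WT cells differed in H3K27ac at fewer places than early cells, and the balance of rising and falling bins moved with single libraries. Late KO and late WT libraries shared 71.0% of covered windows on average, against 78.0% between the KO and 76.5% between the WT replicates. Of 31772 merged regions, 1799 were found in both KO and neither WT library and 1292 in both WT and neither KO library, and the other pairings gave 16 to 394. The highest ranking KO-only regions again lay on chromosome 13, at 113328601 to 113334600 (percentile 83.1), and on chromosome 19, at 25108201 to 25115800 (percentile 81.3), followed by chromosome 4 at 124852601 to 124856400 (percentile 76.1, set median 15.9). The highest WT-only regions were on chromosome 13 at 38568601 to 38573000 (percentile 55.3) and chromosome 10 at 128376601 to 128379800 (percentile 53.4, set median 14.8). In the fit on bins 2642 of 39126 differed, 1561 higher and 1081 lower (limma, adjusted p under 0.05), and 1193 (76.4%) of the bins that rose had no island in either WT library. On chromosome 4 the bin at 140390001 to 140400000 was listed at 0 in late WT and covered 9.1 ± 1.27 kb in late KO (SD, n = 2, limma adjusted p = 0.00105). It sat in a run from 140380001 to 140460000 whose coverage was 10.3 ± 0.1 kb in WT and 35.5 ± 5.2 kb in KO. The bin at 138780001 to 138790000 of the same chromosome went from 0 to 7.9 ± 1.27 kb (adjusted p = 0.00112), and that on chromosome 17 at 11750001 to 11760000 from 0 to 6.9 ± 0.42 kb (SD, n = 2, limma adjusted p = 0.00105). Coverage fell most on chromosome 6 at 41710001 to 41720000 (7.6 ± 0.0 kb in WT), chromosome 19 at 29210001 to 29220000 (6.3 ± 1.84 kb in WT) and chromosome 14 at 44730001 to 44740000 (5.8 ± 0.57 kb in WT), all listed at 0 in late KO (SD, n = 2, limma adjusted p = 0.00105 for each). With the upper 50% of each list the bin on chromosome 19 no longer passed (adjusted p = 0.996), and 1346 bins differed in all. Without late KO replicate 2 the bins split into 1027 higher and 1035 lower, and without late WT replicate 2 into 1960 and 542. Regions in KO alone numbered 2736 without late KO replicate 1 and 3039 without late WT replicate 2. Without late WT replicate 1 there were 1915 regions in KO alone and 3395 in WT alone. With a library left out its genotype needs an island in 1 library only, so these region counts do not compare the balance.

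Bins that responded at both stages moved the same way in most cases. Of the bins that rose in early KO, 868 also rose in late KO (143.1 expected of independent lists), and 253 fell at both stages (58.7 expected). Opposite calls numbered 37 and 26, against 99.1 and 84.7 expected. Both stages were called with the same estimate of spread per bin, and a bin at 0 in WT could not fall. Independent lists are therefore not a fair baseline for these counts either. The early and late KO changes share no library, and across bins their correlation was 0.371 (Pearson) and 0.343 (Spearman), where bins are not independent replicates. Of the early KO-only regions 743 of 3515 (21.1%) overlapped a late KO-only region and 22 (0.6%) a late WT-only one. The bins that stood out with both stages averaged were on chromosome 8 at 126810001 to 126820000, with 6.4 ± 0.28 kb in early KO and 6.7 ± 0.14 kb in late KO, and on chromosome 7 at 151970001 to 151980000, with 6.4 ± 0.0 and 6.6 ± 0.28 kb. Both were listed at 0 in all 4 WT libraries (SD, n = 2, limma adjusted p = 0.000262 for each). The strongest falls were on chromosome 3 at 95570001 to 95580000, from 5.7 ± 2.12 kb in early WT and 5.5 ± 2.69 kb in late WT to 0 in all 4 KO libraries (SD, n = 2, limma adjusted p = 0.000514), and in the bin on chromosome 14 at 44730001 to 44740000 (adjusted p = 0.000287). On average over the stages 7130 bins differed, 4239 higher and 2891 lower, and 1888 were lower without early WT replicate 1. With the upper 50% of each list 3214 bins differed, and the bin on chromosome 3 no longer passed (adjusted p = 0.271).

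Whether the effect of deletion differed between stages was tested as an interaction. It differed in 3966 bins, of which 1547 had a higher and 2419 a lower KO change in late than in early cells (limma, adjusted p under 0.05). The bin on chromosome 7 at 148160001 to 148170000, which gained H3K27ac in early KO, was covered over all of its 10 kb in late WT and in late KO cells alike (limma interaction adjusted p = 0.00286). A bin cannot hold more than 10 kb, so a gain in late KO could not be seen there. The bin on chromosome 4 at 107800001 to 107810000 had 1.9 ± 0.99 kb in late WT and 7.5 ± 0.99 kb in late KO (SD, n = 2, limma interaction adjusted p = 0.0104). On chromosome 6 the bin at 41710001 to 41720000 had no island in any early library or in late KO, and 7.6 ± 0.0 kb in late WT (SD, n = 2, limma interaction adjusted p = 0.00286). The split depended on single libraries. Bins with a higher KO change in late cells numbered 771, 874 and 947 without early WT replicate 1, early WT replicate 2 and late KO replicate 2, and those with a lower one 1514 without early KO replicate 1. Without late WT replicate 2 the split turned, to 1794 and 1754. With the upper 50% of each list the interaction called 2198 bins.

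H3K27ac also changed with time in WT cells, from the early to the late stage. Coverage rose in 3733 bins and fell in 2648 (limma, adjusted p under 0.05), and without late WT replicate 2 it rose in 2521 and fell in 2763. The largest rises were on chromosome 7 at 148160001 to 148170000, from 0 to 10 ± 0 kb, and on chromosome 9 at 123960001 to 123970000, from 0 to 9.6 ± 0.57 kb (SD, n = 2, limma adjusted p = 0.000282 for each). In late KO the bin on chromosome 9 covered 8.7 ± 0.71 kb. The largest falls were on chromosome 11 at 52080001 to 52090000 (adjusted p = 0.000282) and chromosome 18 at 80850001 to 80860000 (adjusted p = 0.000836), each from 10 ± 0 kb to 0, while late KO cells kept 2.4 ± 0.28 and 3.4 ± 1.98 kb (SD, n = 2, limma). The changes with time and those in early KO went the same way far more often than not. Of the bins that rose in early KO 1512 also rose with time in WT (342.3 expected of independent lists) and 30 fell (242.8 expected), and of those that fell 1233 also fell with time (143.7 expected) and 40 rose (202.6 expected). Both comparisons use the early WT libraries, so independent lists are not a fair baseline for these counts, and no count was simulated for shared libraries. With 1 early WT library in each change, bins at least 1 log2 unit higher in KO had median changes with time of 0.042 and 0.199. The median over all bins was 0.042 in both assignments. Across bins the changes correlated at 0.524 with a covariance of 0.5354, where simulated unchanged groups with a shared control gave 0.5 and 0.1022, so part of the excess may come from the shared libraries. The run on chromosome 18 at 12760001 to 12820000 had 30.4 ± 2.5 kb in late WT, above its level in early KO. The run on chromosome 4 at 119730001 to 119810000, lost in early KO, had no island in late WT (0.0 ± 0.0 kb) and 2.8 ± 0.3 kb in late KO (SD, n = 2). With the upper 50% of each list 3023 bins changed with time, and the bin on chromosome 18 at 80850001 no longer passed (adjusted p = 0.109).

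**Figure D3:**
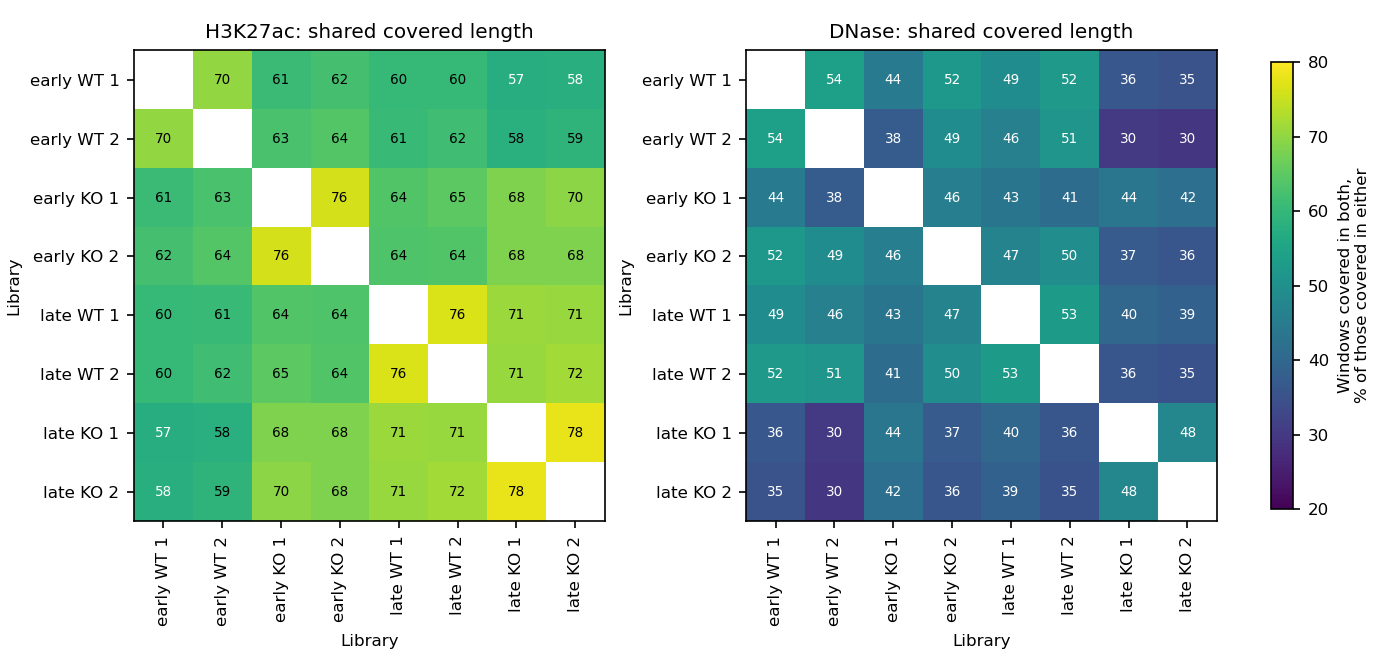
Windows of 200 bp covered in both libraries as a percentage of those covered in either, for each pair of H3K27ac (left) and DNase (right) libraries. H3K27ac replicates share 70.3% to 78.0%, late KO and late WT libraries 70.7% to 71.6%, and the DNase lists of late KO share 29.5% to 36.4% with those of early WT.

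DNase-seq asked where deletion changed open chromatin. In early cells more open regions were found in WT alone than in KO alone. Of 45847 merged regions, 4327 were open in both WT and neither KO library, 918 in both KO and neither WT library, and 20959 (45.7%) in all 4, while the other pairings gave 18 to 1545. The KO-only regions that ranked highest were on chromosome 19 at 55213201 to 55214800 (percentile 91.3) and chromosome 17 at 15243801 to 15245800 (percentile 91.0, set median 31.8), and among the first 5 were chromosome 19 at 25110801 to 25111800 (percentile 85.5) and chromosome 14 at 71348601 to 71350600 (percentile 84.8). The WT-only regions that ranked highest were on chromosome 11 at 109619001 to 109621000 (percentile 75.1) and chromosome 9 at 80431201 to 80433000 (percentile 72.3, set median 20.5). The WT-only count depended on list length. With lists cut to equal length, WT-only regions numbered 1253 and KO-only regions 1268. In bins, 462 of 37586 differed between early KO and early WT, 203 higher and 259 lower (limma, adjusted p under 0.05). The largest rises were on chromosome 7 at 71220001 to 71230000 (0 in WT, 7.4 ± 0.28 kb in KO), chromosome 17 at 3020001 to 3030000 (0 in WT, 5.9 ± 3.82 kb in KO) and chromosome 4 at 146790001 to 146800000 (0 in WT, 4.4 ± 1.98 kb in KO; SD, n = 2, limma adjusted p = 0.0467 for each). The largest falls were on chromosome 11 at 95000001 to 95010000 (4.8 ± 1.13 kb in WT, 0 in KO), chromosome 6 at 83660001 to 83670000 (8.1 ± 1.84 kb in WT, 0.6 ± 0.85 kb in KO) and chromosome 15 at 11830001 to 11840000 (3.7 ± 0.71 kb in WT, 0 in KO; SD, n = 2, limma adjusted p = 0.0467 for each). Leaving out any one of the 8 DNase libraries left 0 bins past the limma test, with 2441 to 6120 at an unadjusted p under 0.05. This number was 4648 with all libraries, and 2690 and 2441 without early WT replicates 1 and 2. The late libraries do not enter the early difference, and each of these fits has 1 residual degree of freedom less. The bin on chromosome 7 at 71220001 had adjusted p from 0.0691 to 0.476 in them. No bin passed either with a pseudocount of 2 kb, with no filter or with the replicate block (limma, with 4197, 5378 and 4545 bins at an unadjusted p under 0.05). The split was 383 higher and 1521 lower with no centring and 278 and 845 with the upper 50% of each list, and it turned to 650 and 551 with equal list lengths and 9 and 0 with quantile normalization. Without early KO replicate 1 there were 4556 KO-only and 4541 WT-only regions. The KO-only rule then needs an island in 1 library and the WT-only rule in 2, so these counts do not compare the balance. KO-only regions numbered 1443 without early WT replicate 2, and WT-only regions 12205 without early KO replicate 2 and 7967 without early WT replicate 1.

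In late cells the DNase lists of KO held fewer regions. Of 37476 merged regions, 8122 were open in both WT and neither KO library and 358 in both KO and neither WT library, while the other pairings gave 11 to 391. Late KO and late WT libraries shared 37.4% of covered windows on average, against 47.7% between the KO and 52.6% between the WT replicates, and with equal list lengths 44.8% against 48.0% and 57.9%. KO-only regions were led by chromosome 17 at 15243801 to 15246800 (percentile 92.7) and chromosome 4 at 124853001 to 124855400 (percentile 90.4, set median 30.3), and WT-only regions by chromosome 11 at 102177001 to 102182200 (percentile 81.6) and chromosome 9 at 86249201 to 86252600 (percentile 80.4, set median 30.9). In the fit on bins 811 differed, 129 higher and 682 lower (limma, adjusted p under 0.05). Of these, 120 (93.0%) of the higher and 627 (91.9%) of the lower bins had no island in either library of the lower group. The largest rises were on chromosome 17 at 3010001 to 3020000 (0 in WT, 9.1 ± 0.42 kb in KO, adjusted p = 0.0123) and 3030001 to 3040000 (0 in WT, 8.2 ± 0.0 kb in KO, adjusted p = 0.0153), and on chromosome 5 at 120790001 to 120800000 (0 in WT, 6.7 ± 0.14 kb in KO, adjusted p = 0.0123; SD, n = 2, limma). The largest falls were on chromosome 2 at 11610001 to 11620000 (8.5 ± 0.99 kb in WT, adjusted p = 0.0325), chromosome 3 at 60280001 to 60290000 (6.3 ± 0.42 kb in WT, adjusted p = 0.0123) and chromosome 6 at 83660001 to 83670000 (5.6 ± 1.13 kb in WT, adjusted p = 0.0283), each listed at 0 in KO (SD, n = 2, limma). The fall of the bin on chromosome 6 changed its sign with equal list lengths and with the upper 50% of each list, neither past the test. No bin passed without early WT replicate 1 or 2 or late WT replicate 1 or 2 (limma, with 5589, 5627, 5790 and 4608 bins at an unadjusted p under 0.05), and 402 and 195 passed without late KO replicates 1 and 2. With a pseudocount of 2 kb 162 passed, 62 higher and 100 lower, and with the upper 50% of each list 104 were higher and 1167 lower. With the replicate block 96 passed, 21 higher and 75 lower. The split was 156 higher and 2574 lower with no centring, 131 and 200 with quantile normalization, and 695 and 484 with equal list lengths, so the direction of the late DNase calls turned with list length. Equal list lengths also gave 1430 WT-only and 1205 KO-only regions. Without late WT replicate 1 there were 17399 WT-only regions, and KO-only regions numbered 671, 788 and 653 without late KO replicate 1, late KO replicate 2 and late WT replicate 2. Without centring the median DNase bin changed by -0.34 in early and -0.53 in late KO on the log2 scale, against -0.09 and -0.17 with it. DNase changes are given with centring, where 0 is set by bins covered in all 8 libraries and not by the median bin.

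**Figure D4:**
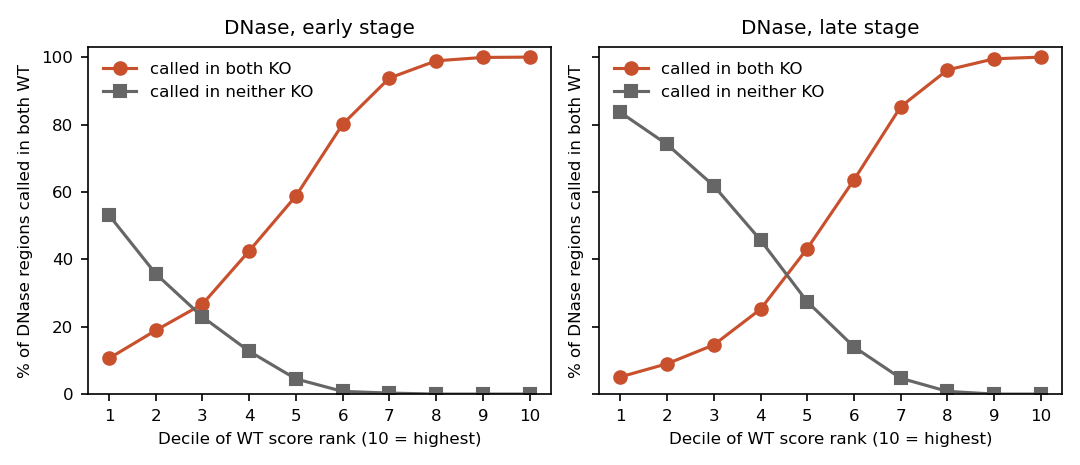
DNase regions called in both WT libraries, by decile of their score rank in WT (10 is highest), for early (left) and late (right) cells; lines give the percentage called in both KO libraries and in neither. In late cells 83.6% of the lowest decile and 0.0% of the highest were called in neither KO library.

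Averaged over both stages 581 DNase bins differed, 245 higher and 336 lower, and the interaction called 0 bins (limma, with 5022 at an unadjusted p under 0.05). The interaction count depended on the scaling, with 1939 bins with no centring, 691 with equal list lengths and 1136 with the upper 50% of each list, so a difference between stages is not excluded. The number of calls for the average moved with single libraries. It gave 0 bins without early WT replicate 1, early WT replicate 2 or late WT replicate 1 (limma, with 5258, 5079 and 7266 at an unadjusted p under 0.05), 4 without late WT replicate 2, 10 without early KO replicate 1, 1 without late KO replicate 1, 20 without late KO replicate 2 and 1074 without early KO replicate 2. Its split was 446 higher and 3940 lower with no centring, 236 and 138 with quantile normalization, 1164 and 626 with equal list lengths, 141 and 107 with a pseudocount of 2 kb, 65 and 123 with no filter and 335 and 899 with the upper 50% of each list. With the replicate block it was 7 higher and 1 lower. Early and late DNase changes correlated at 0.23 (Pearson) and 0.188 (Spearman) across bins, and at 0.138 (Pearson) without early KO replicate 1. From early to late WT 1018 DNase bins changed, 223 higher and 795 lower. This too depended on the scaling, with 1 bin with quantile normalization, 506 higher and 659 lower with equal list lengths, and 399 and 1473 with no centring. The bin on chromosome 11 at 52080001 to 52090000, which lost H3K27ac over the same interval, fell from 6.5 ± 0.42 kb to 0, and that on chromosome 10 at 116350001 to 116360000 from 5.2 ± 0.85 kb to 0 (SD, n = 2, limma adjusted p = 0.0317 for each). Rises led on chromosome 4 at 146790001 to 146800000 (0 to 4.9 ± 0.42 kb, adjusted p = 0.0317, with its sign changed by the upper 50% of each list) and chromosome 9 at 123740001 to 123750000 (0 to 4.8 ± 0.85 kb, SD, n = 2, limma adjusted p = 0.0493). No bin changed with time without early WT replicate 1 or 2, late WT replicate 1 or 2 or late KO replicate 1 (limma, with 3238, 2960, 4095, 6309 and 4879 at an unadjusted p under 0.05), 1 did without late KO replicate 2, and 1624 did without early KO replicate 2. None did with a pseudocount of 2 kb, with no filter or with the replicate block (limma, with 5032, 5004 and 5065 at an unadjusted p under 0.05).

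The assays were then set against each other. Where H3K27ac was gained in KO, open chromatin was found more often too. Of the early KO-only DNase regions 290 of 918 (31.6%) overlapped a KO-only H3K27ac region and 3 (0.3%) a WT-only one, and of the late ones 125 of 358 (34.9%) and 1 (0.3%). DNase regions open in all 4 libraries overlapped a KO-only H3K27ac region in 4.7% of early and 0.9% of late cases. WT-only DNase regions overlapped WT-only H3K27ac regions in 184 of 4327 early cases (4.3%, against 2.2% for KO-only H3K27ac) and 264 of 8122 late cases (3.3%, against 1.0%). In bins where H3K27ac rose in early KO the median DNase change was a log2 of 0.21 (2605 bins), in bins where it fell -0.36 (1088 bins), and in the other bins -0.08 (26429 bins). The late medians were 0.36, -0.53 and -0.21. After centring, a bin without islands in any early DNase library (chromosome 2 at 9770001 to 9780000) had an early change of 0.25. One without islands in any late DNase library (chromosome 5 at 28490001 to 28500000) had a late change of 0.36. The medians where H3K27ac rose therefore show a difference from the other bins, and no DNase gain by themselves. Across 30122 bins the KO changes of the assays correlated at 0.237 (Pearson) and 0.184 (Spearman) in early and 0.193 and 0.146 in late cells, and the assays share no library. The early correlation was 0.147 (Pearson) without DNase early KO replicate 2.

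KO-only regions of both assays at both stages joined in 44 merged regions and WT-only regions in 10, by a match that was set after the data were seen. Of the 44 merged regions 5 also held an island of a WT library, and of the 10 1 held an island of a KO library. On chromosome 19 the region at 25108201 to 25115800 had 5.7 ± 0.4 kb of H3K27ac in early KO and 7.4 ± 0.0 kb in late KO, with 0.8 ± 0.3 and 1.4 ± 1.1 kb of DNase islands. On chromosome 7 at 151966201 to 151976800 H3K27ac covered 8.4 ± 2.5 and 7.8 ± 1.1 kb and DNase islands 2.8 ± 1.1 and 3.1 ± 0.7 kb. The region on chromosome 9 at 114258801 to 114265200 had 6.0 ± 0.0 and 6.3 ± 0.1 kb of H3K27ac and 1.3 ± 0.1 and 0.9 ± 0.1 kb of DNase islands, and that on chromosome 5 at 34947201 to 34953000 had 5.1 ± 0.1 and 5.7 ± 0.1 kb and 0.9 ± 0.7 and 0.8 ± 0.0 kb. WT libraries had no island of either assay in these 4 regions. Of the WT-only regions, the widest lay on chromosome 17 at 57035801 to 57049400, with 12.0 ± 1.4 kb of H3K27ac in early WT and 2.5 ± 0.1 kb in late WT. On chromosome 9 at 80429401 to 80433800 H3K27ac covered 4.0 ± 0.6 kb in early and 3.8 ± 0.3 kb in late WT, and on chromosome 3 at 65660001 to 65664000 it covered 2.6 ± 0.0 and 3.7 ± 0.1 kb (SD, n = 2 per group). The KO libraries had no island of either assay in these 3 regions.

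**Figure D5:**
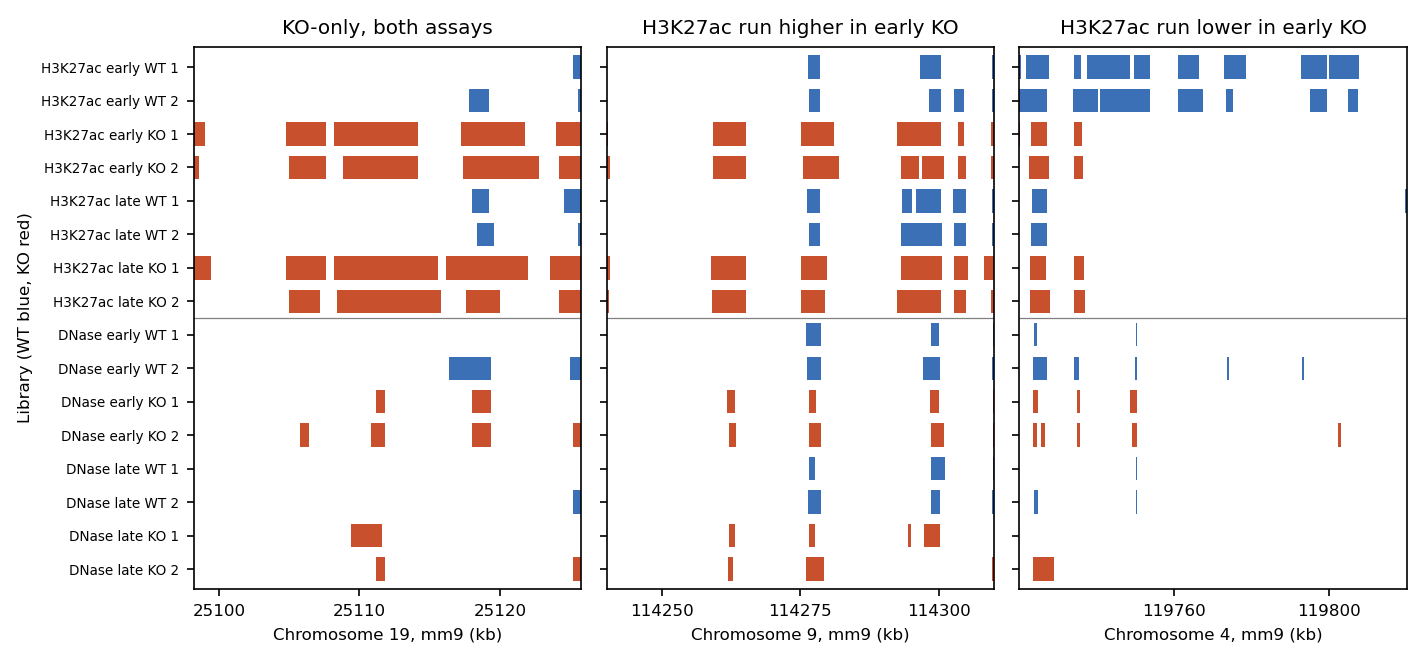
Islands of each library along regions of chromosomes 19, 9 and 4 (position in kb on mm9), blue for WT and red for KO, with H3K27ac above the line and DNase below it. The region on chromosome 19 shows islands between 25108201 and 25115800 in KO libraries alone, and the run on chromosome 4 shows H3K27ac islands of early WT most of which the other groups lack.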

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

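The test that splits the early WT libraries, the use of the upper 50% of each list for the covariance below and the count of splits within stages were chosen only after the results were seen. The effect of deletion on H3K27ac differed between early and late cells in 3966 bins by the interaction test. Of the first 3 bins per direction named for KO against WT at either stage, 7 are among them. The interaction log2 was -2.34 on chromosome 4 at 107800001 to 107810000, -3.99 on chromosome 7 at 148160001 to 148170000 and 5.70 on chromosome 1 at 93870001 to 93880000. On chromosome 4 it was 1.37 at 140390001 to 140400000 and 3.88 at 138780001 to 138790000. It was -4.02 on chromosome 6 at 41710001 to 41720000 and -3.26 on chromosome 19 at 29210001 to 29220000. Each of these bins was listed at 0 in a group, so these values depend on the pseudocount of 0.5 kb and are no measure of size: with 2 kb the early change of the bin on chromosome 7 was 2.22 in place of 3.95. The bins named for their fall with time also passed, with 2.53 on chromosome 11 at 52080001 and 3.15 on chromosome 18 at 80850001.

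Early KO changes of H3K27ac moved with the change from early to late WT cells, with a covariance of 0.5354 and a correlation of 0.524 across bins. Simulated unchanged groups with a shared control gave a covariance of 0.1022 and a correlation of 0.5. The correlation was thus close to what a shared control gives, and only the covariance stood above it. With 1 early WT library in each change the covariance was 0.3924 and 0.4265 in the 2 assignments, so noise of single early WT libraries alone does not account for it. What both early WT libraries have in common still enters both changes, and this split cannot exclude it. Bins at least 1 log2 unit lower in KO than in 1 early WT library had a median change of -0.709 and -0.847 from the other early WT library to late WT, against a call of fewer weak islands in early WT as the whole cause, while for bins higher in KO it was 0.042 and 0.199, against 0.042 over all bins, so with the libraries split the relation lay mainly in the falling bins. With the upper 50% of each list the covariance was 0.567 over 23334 bins, where simulated unchanged groups gave 0.1309. This cut makes a new limit in each list, at which islands can again be listed or missing. It therefore cannot decide on weak islands of the early WT lists as the cause. Only 6 of the 1360 regions lost in early KO ranked in the upper 50% of both early WT lists (5 of them found in both late WT libraries), so for lost regions weak calls stay open. Whether deletion moved early cells towards the late H3K27ac state was not decided, since a property common to both early WT libraries and an effect of 4-OHT itself stay open.

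Late KO cells had short DNase lists, in which 8122 of the 26024 regions open in both late WT libraries (31.2%) were missing from both. Of the missing regions 93.7% ranked in the lower 50% of the WT ranks, against 17.9% of the regions kept, and lower sensitivity of the late KO libraries could give this. The log2 H3K27ac change at missing minus kept regions of the same WT rank was -0.437 (below 0 on 20 of 20 chromosomes, SD 0.131), which a loss of open sites after deletion would also give. Over all ranks the mean change was -0.122 at missing and 0.031 at kept regions, and the kept ones were chosen for being called in KO, so the difference need not be a fall at the missing ones. The values needed by both explanations are there, and without read numbers their shares stay open.

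Other splits of the 8 libraries into 4 and 4 were counted for the genotype. Each was fitted with the stage as an added term in place of the 4 groups, and the split by stage without a second term. A KO effect that differs between stages then adds to the spread. The counts below are therefore not those of the average over both stages, which called 7130 H3K27ac and 581 DNase bins. For H3K27ac 2 of 35 splits called as many bins as the genotype, so this count alone does not exclude chance. The genotype split called 1696 bins, the highest other split 2548, and that split follows the stage of culture, which points to a structure of the samples; the next highest called 21. For DNase 1 of 35 splits, the genotype itself, called as many (156 bins, highest other 42). That is the lowest share 35 splits allow, and not all of them balance the stages, so chance is not excluded. The 18 splits with 2 libraries of each stage on each side are too few for a share under 0.05, and the genotype called the most bins among them in both assays.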

How the results depend on the processing

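The settings with 50-kb bins and with centring on the mean were chosen only after the results were seen. H3K27ac kept its total counts within 1.5 times under no centring, quantile normalization, equal list lengths, a pseudocount of 2 kb, no filter, the replicate block, centring on the mean and each library left out, while counts by direction moved further with a library left out (lower early 1041, lower late 542, higher interaction 771). It moved with the upper 50% of each list (early 2506, late 1346, average 3214, interaction 2198, time 3023 bins) and with 50-kb bins (3406, 1303, 3977, 1679 and 3891), both of which test fewer islands or bins. DNase counts moved, and the cause was not tested. Early DNase calls numbered 1904 with no centring, 9 with quantile normalization, 1201 with equal lists, 1123 with the upper 50%, 40 with 50-kb bins, and 0 with a 2-kb pseudocount, no filter or the replicate block. Late calls numbered 2730, 331 and 1271 with no centring, quantile normalization and the upper 50%, 162 with a 2-kb pseudocount, 96 with the replicate block and 374 with 50-kb bins. For the average they were 4386, 374, 1790 and 1234 with no centring, quantile normalization, equal lists and the upper 50%, 248 with a 2-kb pseudocount, 188 with no filter, 8 with the replicate block and 881 with centring on the mean. The interaction gave 1939, 691 and 1136 with no centring, equal lists and the upper 50%. Time gave 1872 with no centring, 1 with quantile normalization, 1 with 50-kb bins, and 0 with a 2-kb pseudocount, no filter or the block. Libraries left out in turn gave 0 to 0 early, 0 to 1136 late, 0 to 1074 average and 0 to 1624 time calls in DNase; a lone library was assumed to vary like the other groups.

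Region counts with the upper 50% of each list were, KO-only then WT-only, 1279 and 413 for early H3K27ac, 601 and 455 for late H3K27ac, 437 and 2110 for early DNase and 164 and 4124 for late DNase. Equal lists gave 1253 WT-only regions in early DNase, and 1205 KO-only and 1430 WT-only regions in late DNase. With a library left out, which loosens the rule, H3K27ac gave 3882 to 6296 early KO-only, 1612 to 2869 early WT-only, 1915 to 3039 late KO-only and 1439 to 3395 late WT-only regions. DNase gave 1075 to 4556, 4541 to 12205, 380 to 788 and 8844 to 17399. Correlations of the assays were 0.203 early with quantile normalization, 0.25 late with equal lists and 0.174 late with quantile normalization, and that of early and late DNase changes 0.287 with equal lists. Left-out libraries gave 0.147 to 0.241 and 0.162 to 0.212 between assays (early, late), and 0.349 to 0.372 and 0.138 to 0.271 between stages (H3K27ac, DNase). Of the named H3K27ac bins 284 of 312 values under other settings kept direction and call, 28 lost the call and 0 reversed. Of the DNase ones 95 of 248 kept both, 150 lost the call and 3 reversed: the late fall on chromosome 6 at 83660001 became 0.28 with equal lists and 0.34 with the upper 50%, and the rise with time on chromosome 4 at 146790001 became -0.01 with the upper 50%.

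Same-numbered libraries deviated together with r between -0.038 and 0.082. This gave no sign that replicate numbers pair the samples, but these deviations cannot exclude a shared animal or culture. With the replicate block H3K27ac gave 5282 early, 2355 late, 6470 average, 3512 interaction and 5925 time calls. Gene-based alternatives were not run without an mm9 annotation. Depth is unknown, so a bin at 0 limits no level.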

Other observations

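The values given here were chosen only after the results were seen, and no test was added to them. Regions acetylated in both early WT and neither early KO library numbered 1360 when all 8 H3K27ac libraries were merged, and 793 of them (58.3%) had no island in either late WT library, against 702 of 20250 (3.5%) of the regions kept in early KO. In late KO 85.0% of the 1360 had no island. Regions gained in early KO numbered 3362, and 33.8% of them were found in both late WT libraries and 52.1% in neither. Of the 3540 regions called in no early library, 35.9% were found in both late WT libraries and 25.0% in neither. Regions called in no early library are listed only because a late library called them, which raises their share in late WT. This comparison therefore cannot decide whether gained regions were found more often in late WT. The lost regions were weak ones: 6 of them ranked in the upper 50% of both early WT lists, against 12196 of the kept regions, and of these 6, 5 were found in both late WT libraries.

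Close to the start of chromosome 17, from 3000001 to 3040000, DNase islands appeared in KO libraries alone. They covered 11.0 and 23.0 kb in the early KO replicates and 24.8 and 25.0 kb in the late KO replicates, and 0.0 kb in each of the 4 WT libraries. The same interval of chromosome 3 held 7.8 and 12.0 kb in the late KO replicates and 0.0 kb in the other DNase libraries. H3K27ac islands were absent from both intervals in all 8 libraries. Chromosome 13 from 63180001 to 63240000 gained both measures in KO: H3K27ac covered 3.8 ± 1.7 kb in early WT and 14.2 ± 0.6 kb in early KO, and 3.1 ± 1.8 and 19.5 ± 1.3 kb in late cells, while DNase islands covered 0.8 ± 1.1 and 5.4 ± 1.7 kb in early and 0.0 ± 0.0 and 4.4 ± 0.8 kb in late cells (SD, n = 2).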
